A study of Mus musculus with 42 samples.

How the data were processed

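Transcripts of sorted epithelial cells, crypts and unsorted glands from adult mice, untreated and not selected for sex, were measured on Affymetrix mouse gene arrays. Per the labels, glands were released by chelation, digested to single cells with TrypLE, sorted by fluorescence, and the RNA was amplified to cDNA and labelled with biotin. The deposited table holds log2 intensities per probe set, and per the submitters' processing notes the values come from RMA, with limma 3.26.8, R 3.2.3, oligo and Partek also named there without their order or role. The values ran from 0.574 to 13.61 over 41345 probe sets and 42 arrays, with none missing, and the highest correlation between 2 arrays was 0.987. No raw array files were used, so background correction and summarization are those of the authors.

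Of the probe sets, 23521 carried 1 gene symbol, 1814 several and 16010 none. The probe sets with 1 symbol gave 22180 genes, and for the 1082 genes with several probe sets the one with the highest mean over all arrays was used. Of the gene identifiers 23328 matched the reference annotation, 193 did not, and 0 symbols changed. Probe sets of near-identical family members, such as the defensins, can share signal.

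Arrays were grouped by the titles into 15 groups of 3 mouse models. The mouse model field of the 9 DTR arrays names the other reporter line, and the title was followed. The unsorted and crypt groups of small intestine and the unsorted colon group entered the fit of their model but no comparison of genes. The whole colon array numbered 1 had a gastric profile and was kept in the fit of its model, and a fit without it was also run. Its difference from the other whole colon array enters the residual spread of every IRES comparison. That widens the standard errors of genes that differ between stomach and colon, so such genes can miss a call.

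For each model a linear model with 1 mean per group was fitted in limma 3.58.1 (R 4.3.3), with eBayes moderation and Benjamini-Hochberg adjustment over all genes, and a gene was called at an adjusted p under 0.05. The p-values measure the spread between samples that the labels call biological replicates. The differences between organs were tested as a difference of differences. 26 gene lists, 21 of gene programmes and 5 of cell type markers, were written before the data were examined, as were the groups, the comparisons and most of the other settings. A list was tested where at least 3 members were measured, with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether members move 1 way on balance and does not compare them with other genes. Lgr5, the sort marker, is a member of 3 lists. Lists share further members, so their results are not independent. The Wnt target, intestinal stem cell and gland base lists also share Sox9 and Axin2. The pit cell and gastric identity lists share Gkn1 and Tff1. The pyloric set holds genes at least 2-fold higher, with an adjusted p under 0.05, in IRES pyloric Lgr5Hi cells than in each of 5 other sorted IRES populations.

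Genes were named by a rule: Lgr5 and Aqp5 always, then for each comparison the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, and up to 4 members of each list with the smallest p, called ones first. Unnamed gene models and sex-linked genes were left out of the largest changes, and the text names a part of each list from its top or the members that were called. For the pyloric set the rule named the 20 genes with the largest smallest difference. Groups of 4 arrays against 4 part without overlap by chance in 2.86% of genes and groups of 3 against 3 in 10%.

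The replicate numbers were checked for pairing by correlating the deviations of equally numbered arrays from their group means across genes. In the IRES pylorus r was 0.16, 0.10, 0.27 and 0.30 and in the colon 0.18, 0.14 and 0.24, positive in each, so the block on the replicate number is reported beside those results. In the small intestine it was 0.37 for each of 2 pairs, fewer than the 3 that the rule asked for. In the DTR line it ran from -0.11 to 0.15 and in WT from -0.02 to 0.17, and these were treated as unpaired.

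The fit was tested on simulated data with 100 changed genes at each size of change and independent normal errors. Their spread was the residual spread of all arrays of a model. The IRES tissues thus shared a spread that held the gastric-like whole colon array, and their rates differ in array numbers and random draws only. At a log2 difference of 2 the fit recovered 99 in each DTR comparison, 97 in the IRES pylorus, 91 in WT, 91 in the colon and 89 in the small intestine, and at a difference of 1 it recovered 68, 73 and 69, 49, 45, 32 and 15. For the difference of differences these were 62 and 79 at 2, and 6 and 16 at 1, against small intestine and colon. False calls made up 2.06% to 8.89% of the calls.

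Other settings chosen beforehand were a block on the replicate number, the mean of all probe sets of a gene, removal of dim probe sets, quantile normalization, 1 fit over all 42 arrays, trend and robust moderation, a 2-fold threshold and leaving out each replicate in turn. Where that left 1 array in a group, the lone array was assumed to vary like those of the other groups. 5 further settings were chosen after seeing the data, namely the fit and the list tests without the gastric-like whole colon array, the block and quantile normalization for lists, and the block for correlations between models. Tables were prepared and figures drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.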

Results

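Transcript levels were measured on Affymetrix arrays in 42 samples of mouse gastrointestinal epithelium from untreated adult animals. 25 samples came from the Lgr5-EGFP-IRES-CreERT2 line, a reporter in which green fluorescence marks cells that transcribe Lgr5, a Wnt target gene and stem cell marker. From its pylorus, the outlet region of the stomach, came 4 samples of brightly fluorescent cells (Lgr5Hi), 4 of dim cells (Lgr5Lo) and 2 of unsorted tissue. Its small intestine gave 2 Lgr5Hi, 2 Lgr5Lo, 2 crypt samples and 1 unsorted sample. Its colon gave 3 Lgr5Hi, 3 Lgr5Lo and 2 unsorted samples. The pylorus of a second reporter line, Lgr5-EGFP-DTR, gave 3 samples each of Lgr5Hi, Lgr5Lo and unlabelled (Lgr5Neg) cells. Wildtype pylorus was sorted with an antibody against Aqp5, a water channel, into 4 Aqp5Pos and 4 Aqp5Neg samples. The lines are called IRES, DTR and WT below. The array medians lay between 3.82 and 4.25 on the log2 scale, and the precision of each value is limited by the number of arrays per group. The values carry no detection calls, so a difference from a group near or below these medians, and close to background, is read as a lower bound. Differences are log2 values followed by their standard error, and group levels are means with the SD.

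Lgr5 followed the gates in each sorted tissue, and Aqp5 was high in the pylorus and low elsewhere. In the IRES pylorus Lgr5 stood at 8.53 ± 0.50 (SD, n = 4) in Lgr5Hi cells and 6.51 ± 0.37 (n = 4) in Lgr5Lo cells. In the small intestine it stood at 8.34 ± 0.03 (n = 2) and 5.86 ± 0.48 (n = 2), and in the colon at 7.69 ± 0.67 (n = 3) and 5.79 ± 0.68 (n = 3). The DTR gates held 8.73 ± 0.08, 6.59 ± 0.38 and 4.60 ± 0.24 (n = 3 each) from Lgr5Hi to Lgr5Neg. Sorting wildtype cells on Aqp5 protein, without any Lgr5 reporter, also parted Lgr5. The level stood at 8.38 ± 0.47 in Aqp5Pos and 6.42 ± 0.17 in Aqp5Neg cells (n = 4 each). Aqp5 stood at 9.98 ± 0.66 in IRES pyloric Lgr5Hi cells and 8.17 ± 0.51 in Lgr5Lo cells. It was at 10.44 ± 0.05, 9.52 ± 0.20 and 7.70 ± 0.07 in the DTR gates, and at 8.82 ± 0.40 and 7.18 ± 0.19 in Aqp5Pos and Aqp5Neg cells. In the intestinal and colonic groups its mean lay between 4.34 and 4.92.

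**Figure D1:**
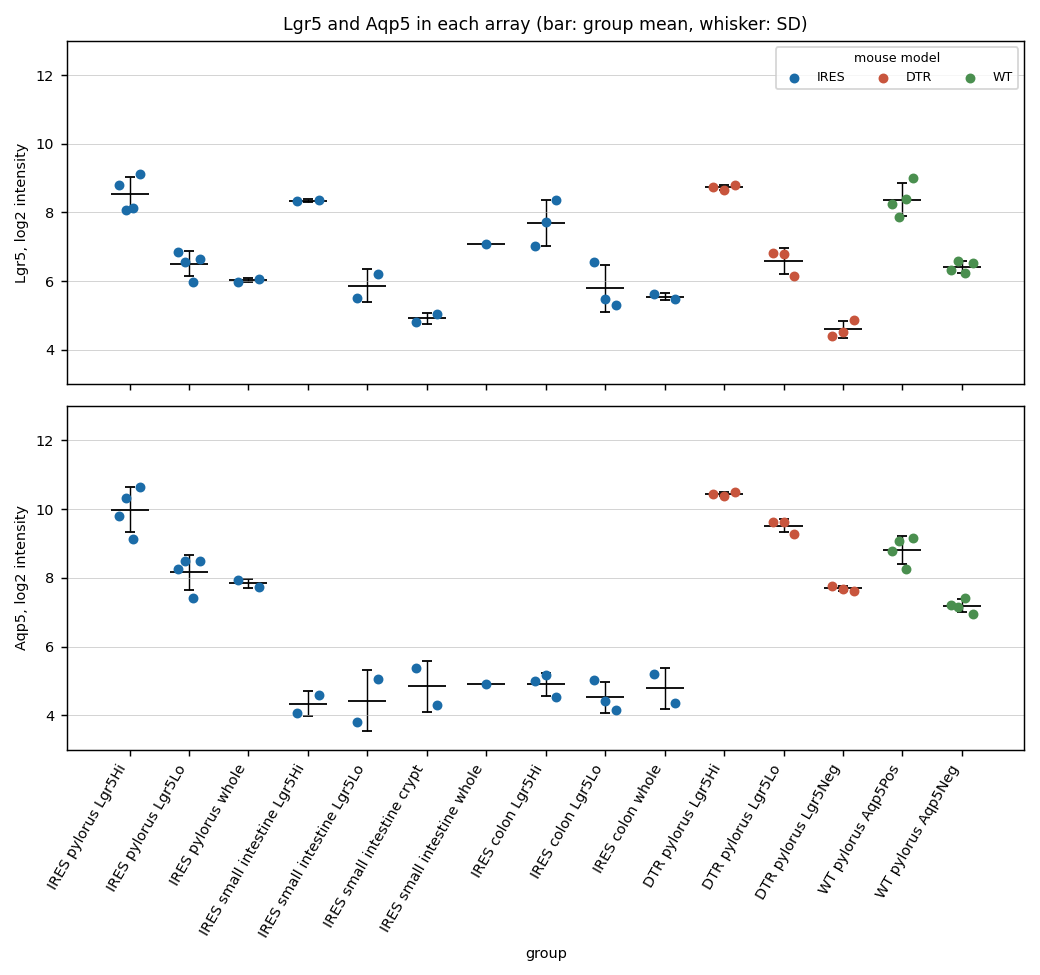
Level of Lgr5 (upper panel) and Aqp5 (lower panel) in each of the 42 arrays, as log2 intensity on the vertical axis, by group on the horizontal axis and coloured by mouse model. The bar is the group mean and the whisker the SD. Aqp5 is at 9.98 in IRES pyloric Lgr5Hi cells and at no more than 4.92 in the mean of any intestinal or colonic group.

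The DTR line compares the brightest cells with cells that lack the reporter, and so asks what sets pyloric Lgr5-expressing cells apart from the rest of the gland. Lgr5Hi cells held far more transcript of gland base and stem cell genes and of gland secretory genes, and far less of the genes of surface pit cells and of dividing cells, with no list called at an estimated correlation (adjusted p between 0.062 and 0.336). Lgr5 itself was higher by 4.13 ± 0.19 (adjusted p = 7.99e-08) and Aqp5 by 2.75 ± 0.14 (adjusted p = 1.44e-07). Among the genes that rose most were Serpina3n, a serine protease inhibitor (5.77 ± 0.37), Cblif, the gastric intrinsic factor (5.71 ± 0.27), Reg3g, an antimicrobial lectin (4.21 ± 0.41), and Pga5, a pepsinogen (3.98 ± 0.26). They were followed by Cacna2d1, an auxiliary subunit of voltage-gated calcium channels (3.55 ± 0.20), Chad, a matrix protein (3.48 ± 0.14), and Rgs5, a regulator of G protein signalling (3.41 ± 0.37). Lgr5Neg cells lay at 3.66 for Serpina3n and 3.19 for Reg3g, under every array median, so both rises are lower bounds. Sptssb, a subunit of the enzyme that starts sphingolipid synthesis, fell by 5.86 ± 0.33, and Muc5ac, the surface mucin of the stomach, fell by 5.16 ± 0.36. Mucl3 fell by 4.93 ± 0.41, Anxa3 by 4.80 ± 0.27 and Psca by 4.56 ± 0.48. The adjusted p of these genes was at most 4.27e-05, and every Lgr5Hi array lay on the same side of every Lgr5Neg array.

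By list, 13 of 16 measured Wnt target genes rose and 1 fell (14 and 1 adjusted over the list alone), with a mean of 1.22 (camera adjusted p = 1.81e-11, and adjusted p = 0.062 with an estimated correlation). Sox9, a stem cell transcription factor (2.44 ± 0.23), Cd44 (1.63 ± 0.15) and Axin2, a feedback inhibitor of Wnt signalling (1.42 ± 0.13), were among them. Of 18 intestinal stem cell genes 14 rose and none fell (14 and 1 adjusted over the list alone, mean 1.28), among them Kcnq1 (2.26 ± 0.15), Slc12a2 (2.10 ± 0.13) and Lrig1, a brake on growth factor receptors (1.99 ± 0.17). Of 13 gastric stem and gland base genes 9 rose and 1 fell (9 and 2 adjusted over the list alone, mean 1.06). Lgr5, the sort marker, belongs to each of these lists, as do Sox9 and Axin2, so the lists are not independent of each other. Of 10 gland mucous cell genes 8 rose (8 adjusted over the list alone, mean 1.60), with A4gnt, which adds the terminal sugar of gland mucin, at 3.36 ± 0.17 and the secretory transcription factors Creb3l4 (2.42 ± 0.14) and Spdef (1.70 ± 0.15). Of 11 surface pit cell genes 8 fell and 1 rose (8 and 2 adjusted over the list alone, mean -2.37), among them the gastrokine Gkn1 (-3.93 ± 0.17) and the trefoil peptide Tff1 (-2.26 ± 0.14). All 16 G1/S genes and all 22 G2/M genes fell, also when adjusted over the list alone, each list by a mean of -1.44. Rrm2, a subunit of ribonucleotide reductase, was at -2.03 ± 0.23, the mitotic gene Birc5 at -1.95 ± 0.25 and Ccna2, a cyclin, at -1.52 ± 0.17. Tuft cell genes were higher too, with 11 of 18 up (12 adjusted over the list alone, mean 1.05), including the lineage factor Pou2f3 (1.51 ± 0.22) and the cation channel Trpm5 (1.77 ± 0.28). Camera called each of these lists at an adjusted p of 5.43e-06 or less. With an estimated correlation each call was lost, at an adjusted p of 0.062 for the stem cell, gland base, mucous and pit cell lists, 0.14 for G1/S, 0.179 for G2/M and 0.336 for tuft cell genes. Fry called each of these lists, at an adjusted p of 0.0383 or less.

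Further lists called by camera in this comparison were the chief and parietal cell genes (3 of 7 higher, 4 adjusted over the list alone, mean 1.73, adjusted p = 0.062 with an estimated correlation) and the gastric identity genes (1 higher and 6 lower of 12, the same adjusted over the list alone, mean -1.13, adjusted p = 0.197 with an estimated correlation). So were the ER chaperone genes (4 of 14 higher, 6 adjusted over the list alone, mean 0.46, adjusted p = 0.197 with an estimated correlation) and the pancreatic acinar genes (3 of 7 higher, also adjusted over the list alone, mean 0.92, adjusted p = 0.196 with an estimated correlation). Fry called all of these further lists as well, at an adjusted p of 0.00131 or less. The gastric identity list shares Gkn1 and Tff1 with the pit cell list, so its fall is in part the same result. The acinar list rested on Clps, a colipase (3.03 ± 0.29), Cela1, an elastase (2.16 ± 0.17), and Try4 (0.93 ± 0.14). Not called were the lists of enteroendocrine (mean -0.12), enterocyte (-0.15), colonocyte (-0.07), Paneth (0.55), goblet cell (-0.79) and intestinal identity genes (-0.35). Nor were those of immediate early (0.00), aquaporin (0.46), Notch (0.10) and EGF family genes (-0.13), or those of immune cells (-0.16), fibroblasts and smooth muscle (0.02), endothelial cells (0.10) and squamous forestomach (-0.14). The enteroendocrine and enterocyte lists had a mean below and a median above 0, camera pointed up for both, and the Paneth list had a mean above and a median below 0. In total limma called 4062 of 22180 genes, 1960 higher and 2102 lower, of which 1247 changed at least 2-fold. 1 fit over all 42 arrays called 1515, and of the 33 genes named here it lost Tff1 (adjusted p = 0.149) and Try4 (adjusted p = 0.284).

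Within the reporter-bearing cells, DTR Lgr5Hi against Lgr5Lo asks what distinguishes the brightest cells from their dimmer neighbours. Cell cycle and pit cell genes were again lower in Lgr5Hi cells, and tuft cell genes stood out on the higher side, each list at an adjusted p between 0.101 and 0.115 with an estimated correlation. Lgr5 rose by 2.14 ± 0.19 (adjusted p = 0.000128) and Aqp5 by 0.92 ± 0.14 (adjusted p = 0.00259). Serpina3n (3.07 ± 0.37) and Cblif (2.32 ± 0.27) rose most, followed by the transcription factor Spib (2.27 ± 0.44), the adaptor gene Sh2d6 (2.18 ± 0.44) and Alox5, the first enzyme of leukotriene synthesis (2.18 ± 0.45), all 3 on the tuft cell list. Sptssb fell by 3.64 ± 0.33, Muc5ac by 3.62 ± 0.36, Gkn1 by 3.22 ± 0.17, Gkn2 by 3.13 ± 0.27 and Atp4b, a subunit of the acid pump of parietal cells, by 3.56 ± 0.55. The adjusted p of these genes was at most 0.0155, and their arrays did not overlap between the groups.

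Of 18 tuft cell genes 13 rose (15 adjusted over the list alone, mean 1.40, camera adjusted p = 1.4e-15, and adjusted p = 0.115 with an estimated correlation), including Dclk1 (2.04 ± 0.36), Hpgds, a prostaglandin D synthase (1.98 ± 0.37), and Pou2f3 (1.72 ± 0.22). The list of G2/M genes fell in 21 of 22 members (22 adjusted over the list alone, mean -1.20, adjusted p = 0.115 with an estimated correlation). The G1/S genes fell in 14 of 16 (16 adjusted over the list alone, mean -1.20, adjusted p = 0.107 with an estimated correlation), with Hells at -1.99 ± 0.33, Mcm5 at -1.61 ± 0.22 and Birc5 at -1.56 ± 0.25. Pit cell genes fell in 6 of 11 (6 lower and 1 higher adjusted over the list alone, mean -1.75) and gastric identity genes in 4 of 12 (4 adjusted over the list alone, mean -0.95), with an adjusted p of 0.101 and 0.115 with an estimated correlation. The pit cell and gastric identity lists share members, Gkn1 among them. Wnt target genes rose in 8 of 16 members and fell in 1 (12 and 1 adjusted over the list alone, mean 0.59), and intestinal stem cell genes rose in 8 of 18 (11 and 1 adjusted over the list alone, mean 0.54). The rise held for gland base genes in 6 of 13 (9 and 2 adjusted over the list alone, mean 0.47) and for mucous cell genes in 5 of 10 (5 adjusted over the list alone, mean 0.48). Smoc2 (2.08 ± 0.27) and Nkd1, a Wnt feedback gene (1.46 ± 0.23), rose, and Myc fell by 1.36 ± 0.17. With an estimated correlation the adjusted p was 0.101 for the first 3 of these lists and 0.174 for the mucous cell genes. Camera also called the pancreatic acinar genes higher (1 of 7, 3 adjusted over the list alone, mean 0.33, adjusted p = 0.383 with an estimated correlation, and 0.0837 by fry). Every other list of this paragraph was called by fry, at an adjusted p of 0.0189 or less. In total 1102 genes were called, 449 higher and 653 lower, of which 369 changed at least 2-fold. The count was 132 in 1 fit over all 42 arrays, and 732, 438 and 325 without Lgr5Hi replicate 1, Lgr5Lo replicate 2 and Lgr5Lo replicate 3. Of the 21 genes named, 9 kept their call in that single fit and 17 without each array in turn, and limma with trend and robust settings lost Sh2d6 (adjusted p = 0.0764) and Alox5 (adjusted p = 0.0856).

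Cells of the dim DTR gate held more transcript of parietal, chief and mucous gland cell genes and of stem cell genes than Lgr5Neg cells. Atp4b (3.98 ± 0.55) and Atp4a (3.42 ± 0.34), the subunits of the acid pump, rose most, followed by Cblif (3.39 ± 0.27), Serpina3n (at least 2.70 ± 0.37, with Lgr5Neg cells at 3.66), Rgs5 (2.64 ± 0.37), A4gnt (2.45 ± 0.17), the gland mucin Muc6 (2.43 ± 0.28) and Pga5 (2.43 ± 0.26). Lgr5 rose by 1.99 ± 0.19 (adjusted p = 0.000224) and Aqp5 by 1.83 ± 0.14 (adjusted p = 3.49e-05). Sptssb fell by 2.21 ± 0.33, the incretin hormone gene Gip by 2.13 ± 0.36 and Aadac, a deacetylase, by 2.09 ± 0.26. The lists of chief and parietal cell genes (5 of 7 higher, 6 adjusted over the list alone, mean 2.08), mucous cell genes (7 of 10, 8 adjusted over the list alone, mean 1.13), intestinal stem cell genes (8 of 18, 12 adjusted over the list alone, mean 0.73), Wnt target genes (6 of 16, 8 adjusted over the list alone, mean 0.63) and gland base genes (5 of 13, 7 adjusted over the list alone, mean 0.59) were called higher by camera with the preset correlation. All 5 were also called with an estimated correlation, at an adjusted p of 0.0128 for chief and parietal cell genes and 0.0298 for the others. No member of the G1/S or G2/M lists was called, and their means were -0.25 and -0.23. Camera called both lower, at an adjusted p of 0.00554 each (adjusted p = 0.514 and 0.522 with an estimated correlation), and fry did not. It also called lower the pit cell (1 of 11, mean -0.62), tuft cell (0 of 18, -0.35), colonocyte (1 of 7, -0.35), goblet cell (3 of 12, and 1 higher, -0.50) and immune cell genes (0 of 21, -0.20). Called higher were the ER chaperone (3 of 14, mean 0.28), aquaporin (2 of 10, 0.30) and pancreatic acinar genes (2 of 7, 0.59). None of these 8 lists was called with an estimated correlation, at an adjusted p between 0.121 and 0.514. Fry called the goblet cell, ER chaperone, aquaporin and pancreatic acinar genes, at an adjusted p between 0.0153 and 0.0358, and not the others. In total 488 genes were called, 348 higher and 140 lower, of which 191 changed at least 2-fold. The count fell to 24 in 1 fit over all 42 arrays, which kept 5 of the 13 genes named. It was 181, 268, 294, 282 and 200 without Lgr5Lo replicates 1 and 2 and Lgr5Neg replicates 1, 2 and 3.

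The equally named gates of the IRES pylorus were compared next. Camera with the preset correlation called the cell cycle lists lower in Lgr5Hi cells, and here the tuft cell list lower as well. With an estimated correlation none of these lists was called (adjusted p = 0.101 for G2/M and G1/S genes and 0.185 for tuft cell genes). By fry all of them were called, at an adjusted p of 0.0373 or less. Lgr5 rose by 2.02 ± 0.30 (adjusted p = 0.00168) and Aqp5 by 1.82 ± 0.35 (adjusted p = 0.00956), in 4 of 4 arrays each. The largest rises were in the small nucleolar RNA gene Snord89 (3.08 ± 0.61), the chemokine gene Cxcl15 (at least 2.70 ± 0.32, with Lgr5Lo cells at 3.23, under the array medians), Serpina3n (2.58 ± 0.46), the radial spoke gene Rsph9 (2.29 ± 0.25), Cacna2d1 (2.18 ± 0.26), Smoc2 (2.10 ± 0.40) and Rgs5 (2.10 ± 0.33). The calcium-binding gene S100g fell by 3.53 ± 0.75, Gnat3, the taste G protein also found in tuft cells, by 2.93 ± 0.61, and the intestinal phosphatase gene Akp3 by 2.58 ± 0.59. Ghrl, which encodes the hormone ghrelin, was 9.22-fold lower. The adjusted p of these genes was at most 0.0351. The G2/M list was lower in 7 of 22 members (17 adjusted over the list alone, mean -0.92, camera adjusted p = 1.18e-18, and adjusted p = 0.101 with an estimated correlation), among them Aurka (-1.42 ± 0.28), Cdc20 (-1.40 ± 0.20) and Birc5 (-1.18 ± 0.21). The G1/S list was lower in 3 of 16 (6 adjusted over the list alone, mean -0.65, adjusted p = 0.101 with an estimated correlation).

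Camera also called the tuft cell genes lower (2 of 18, 7 adjusted over the list alone, mean -0.87, adjusted p = 0.185 with an estimated correlation) and the enteroendocrine genes lower (2 of 26, 6 adjusted over the list alone, mean -0.68, adjusted p = 0.165 with an estimated correlation). It called the enterocyte genes lower as well (0 of 17, 5 lower and 1 higher adjusted over the list alone, mean -0.75, adjusted p = 0.425 with an estimated correlation, and 0.2 by fry). Neurog3, the factor that starts enteroendocrine differentiation, fell by 1.88 ± 0.34, and Siglecf by 1.14 ± 0.28. It called higher the Wnt target genes (1 of 16, 9 adjusted over the list alone, mean 0.66) and the intestinal stem cell genes (5 of 18, 9 adjusted over the list alone, mean 0.65). Also higher were the gland base genes (2 of 13, 5 higher and 1 lower adjusted over the list alone, mean 0.55) and the mucous cell genes (2 of 10, 4 adjusted over the list alone, mean 0.85), with Creb3l4 at 1.74 ± 0.25, Kcnq1 at 1.48 ± 0.26 and Lrig1 at 1.17 ± 0.29. With an estimated correlation the adjusted p of these 4 lists was 0.101, 0.118, 0.134 and 0.101. Fry called these 4 lists and the enteroendocrine genes, at an adjusted p of 0.0276 or less. The ER chaperone genes (0 of 14, also adjusted over the list alone, mean 0.31) were called higher at an adjusted p of 0.317 with an estimated correlation and 0.147 by fry. In total 330 genes were called, 134 higher and 196 lower. With the replicate number as a block 756 genes were called, 315 of them among the 330, and camera then also called the pit cell (mean -0.69), colonocyte (-0.64), goblet cell (-0.62) and immediate early (0.20) lists. 1 fit over all 42 arrays called 780, the fit without the whole colon array numbered 1, whose profile was gastric, called 518, and the counts without Lgr5Hi replicate 2 or 4 were 173 and 174. Of the 21 genes named, 15 kept their call without each array in turn, and trend and robust settings lost S100g (adjusted p = 0.0584), Ghrl (0.0967) and Akp3 (0.0616).

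**Figure D2:**
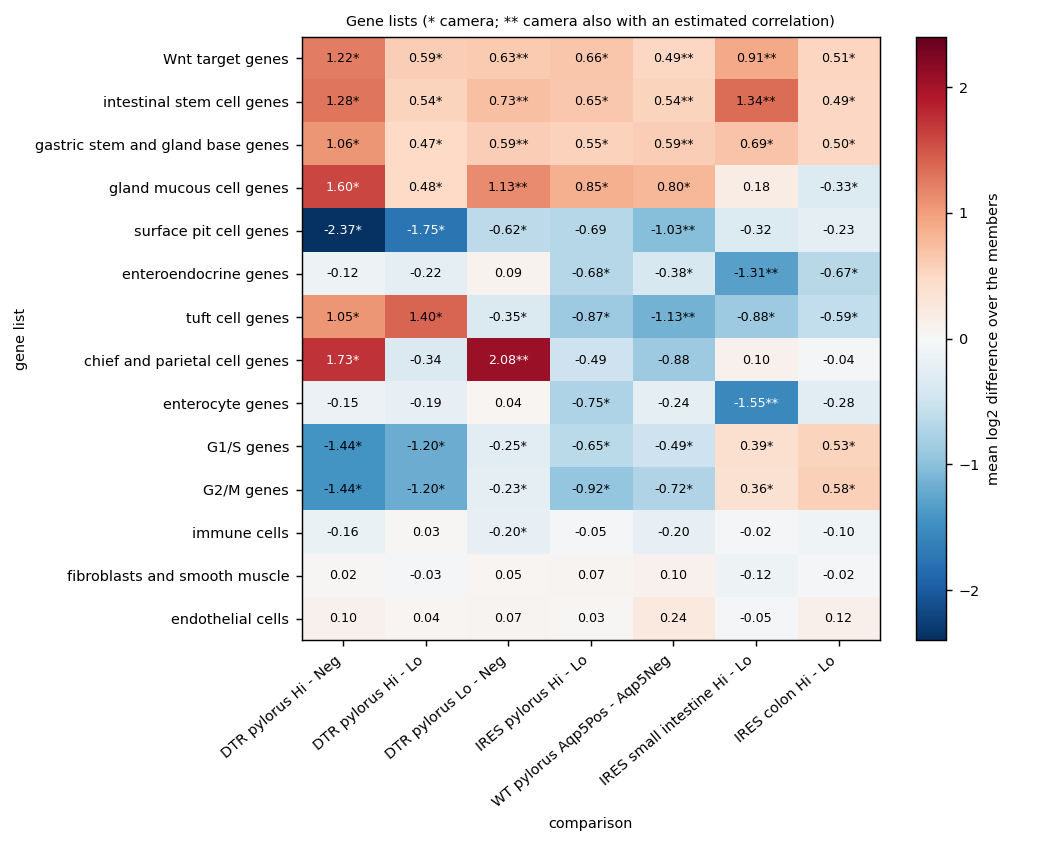
Mean log2 difference over the members of 14 gene lists (rows) in 7 comparisons of sorted cells (columns), red for higher and blue for lower in the population named first. A single asterisk marks a camera call with the preset correlation and a double one a call that also held with an estimated correlation. G2/M genes are at -1.44, -1.20, -0.92 and -0.72 in DTR Hi against Neg, DTR Hi against Lo, IRES Hi against Lo and WT, and at 0.36 and 0.58 in small intestine and colon.

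Against unsorted pylorus, genes of several kinds were far lower in IRES Lgr5Hi cells. The Lgr5Hi cells went through the sort and the unsorted tissue did not, so population and handling cannot be told apart here. Among the largest falls were the Ly6 family genes Ly6g6c (-5.85 ± 0.42) and Ly6d (-5.35 ± 0.49), S100a7l2 (-6.34 ± 0.95), the cornified envelope gene Sprr1a (-5.26 ± 0.89), the iron reductase gene Cybrd1 (-6.33 ± 0.66) and the adipocyte lipid carrier gene Fabp4 (-5.55 ± 0.80). Higher were Mptx1 (5.13 ± 1.35), the heat shock gene Hspa1a (3.98 ± 0.70), Reg3g (3.60 ± 0.95), Bex4 (3.35 ± 0.35) and Serpina3n (3.13 ± 0.56), with Lgr5 at 2.51 ± 0.37 (adjusted p = 0.000163) and Aqp5 at 2.14 ± 0.43 (adjusted p = 0.00282). Hspa1a is on the list of immediate early and dissociation stress genes. That list had 2 of 17 members higher and 1 lower (mean 0.23), and camera did not call it (adjusted p = 0.984). EGF family genes were lower (4 of 11, 5 adjusted over the list alone, mean -0.65, adjusted p = 0.0419 with an estimated correlation), led by the receptor gene Egfr (-2.34 ± 0.25). Camera with the preset correlation also called fibroblast and smooth muscle genes lower (4 of 11, 5 adjusted over the list alone, mean -0.85, adjusted p = 0.14 with an estimated correlation), led by Dcn (-2.55 ± 0.51). Called higher were Wnt target genes (7 of 16, 10 adjusted over the list alone, mean 1.06) and intestinal stem cell genes (9 of 18, 11 adjusted over the list alone, mean 1.11), both at an adjusted p of 0.138 with an estimated correlation. So were gland base (5 of 13, mean 0.89), mucous cell (5 of 10, 1.16) and pancreatic acinar genes (1 of 7, 0.81). Pit cell (2 of 11, mean -1.66), enteroendocrine (1 of 26, -0.45), G1/S (0 of 16, -0.35) and G2/M genes (6 of 22, -0.87) were called lower. None of these 7 lists was called with an estimated correlation, at an adjusted p between 0.138 and 0.558. Fry called all of them but the pit cell, enteroendocrine and G1/S genes. In total 1326 genes were called, 367 higher and 959 lower. The count was 507 and 304 without whole replicate 1 and 2. Of the 15 genes named, 10 kept their call without each array in turn, and trend and robust settings lost Mptx1 (adjusted p = 0.0769) and Reg3g (0.0734).

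In the small intestine the equally named gates parted stem cell genes from enteroendocrine and enterocyte genes, and cell cycle genes did not fall. Lgr5 rose by 2.48 ± 0.43 (adjusted p = 0.0172) and Aqp5 was at -0.09 ± 0.49 (adjusted p = 1). Among the largest changes were Cyp2e1, a cytochrome P450 (2.90 ± 0.30), Wfdc10 (2.11 ± 0.37), Agr3 (2.09 ± 0.42), Afp, the alpha-fetoprotein gene (-3.56 ± 0.38), Reg3a (-3.42 ± 0.57) and the irritant channel gene Trpa1 (-2.80 ± 0.37). Reg3a had an SD of 2.31 in Lgr5Hi and 0.23 in Lgr5Lo cells. Its standard error is pooled over all IRES groups and understates the spread of the former. Trpa1 lay at 3.43 in Lgr5Hi cells, under every array median, so its fall is a lower bound. Intestinal stem cell genes were higher (3 of 18, 12 adjusted over the list alone, mean 1.34, adjusted p = 0.00455 with an estimated correlation), as were Wnt target genes (1 of 16, 7 adjusted over the list alone, mean 0.91, adjusted p = 0.0218 with an estimated correlation). Enteroendocrine genes (1 of 26, 17 adjusted over the list alone, mean -1.31, adjusted p = 0.00167 with an estimated correlation) and enterocyte genes (0 of 17, 7 adjusted over the list alone, mean -1.55, adjusted p = 0.0218 with an estimated correlation) were lower, and so was the tuft cell list (0 of 18, also adjusted over the list alone, mean -0.88, adjusted p = 0.0828 with an estimated correlation, 0.155 by fry). The 2 Lgr5Hi arrays lay far apart for the enterocyte genes Sis and Lct (SD 3.00 and 2.30, against 0.77 and 0.74 in Lgr5Lo cells). Camera also called gland base genes higher (1 of 13, 5 adjusted over the list alone, mean 0.69) and colonocyte (0 of 7, also adjusted over the list alone, mean -1.32), goblet cell (0 of 12, 1 adjusted over the list alone, mean -0.89) and ER chaperone genes (0 of 14, also adjusted over the list alone, mean -0.23) lower. With an estimated correlation the adjusted p of these was 0.0828 and, for the last 3, 0.541, and fry called none of them. The G1/S and G2/M means were 0.39 and 0.36, with no member called over all genes or over the list alone, and camera called both lists higher (adjusted p = 0.446 and 0.541 with an estimated correlation, 0.468 and 0.614 by fry). 41 genes were called, 18 higher and 23 lower, with 2 arrays per group. The count was 93 with the replicate number as a block, 155 in 1 fit over all 42 arrays, 69 without the gastric-like whole colon array, 11 with the dim probe sets removed, and 2, 89, 6 and 18 without Lgr5Hi replicate 1, Lgr5Hi replicate 2, Lgr5Lo replicate 1 and Lgr5Lo replicate 2. Of the 7 called genes named, 2 kept their call without each array in turn, and quantile normalization lost Agr3 (adjusted p = 0.0698).

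In the colon, limma called 0 genes between Lgr5Hi and Lgr5Lo cells, with 1000 genes at an unadjusted p under 0.05. Lgr5 stood at 1.90 ± 0.35 (adjusted p = 0.217), Ascl2, a stem cell transcription factor, at 1.37 ± 0.28 (adjusted p = 0.232), and Aqp5 at 0.37 ± 0.40 (adjusted p = 1). By list, camera with the preset correlation called Wnt target genes (2 of 16 higher adjusted over the list alone, mean 0.51), intestinal stem cell genes (3 of 18 higher adjusted over the list alone, mean 0.49) and gland base genes (2 of 13 higher adjusted over the list alone, mean 0.50) higher. It also called higher the G1/S genes (4 of 16 higher adjusted over the list alone, mean 0.53) and G2/M genes (2 of 22 higher adjusted over the list alone, mean 0.58). It called enteroendocrine genes (3 of 26 lower adjusted over the list alone, mean -0.67) and tuft cell genes (0 of 18 adjusted over the list alone, mean -0.59) lower. It also called lower the colonocyte (mean -1.29), intestinal identity (-0.60), ER chaperone (-0.34), mucous cell (-0.33) and EGF family genes (-0.27), with no member called when adjusted over the list alone. The colonocyte genes Krt20, Car4, Slc26a3 and Car1 varied widely between the Lgr5Hi arrays. Their SD was 2.28 to 3.16 there, against 0.41 to 0.79 in Lgr5Lo cells. None of the 12 lists was called with an estimated correlation, at an adjusted p between 0.0979 and 0.525, and fry called none. With the replicate number as a block camera also called the Paneth (mean -0.65), enterocyte (-0.28) and goblet cell (-0.63) lists, and limma again called 0 genes. The count was 20 in 1 fit over all 42 arrays, 2 with the mean of all probe sets of a gene, and 1 without Lgr5Hi replicate 2 or Lgr5Lo replicate 1. Lgr5 was called in the single fit (adjusted p = 0.0166), as was Ascl2 (0.0282), and with the mean of all probe sets (2.20, adjusted p = 0.0494).

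Lgr5Hi cells of the pylorus and of the intestines differed in gastric identity genes, and those of pylorus and small intestine also in proliferation genes, while Lgr5 did not pass the test. Against the small intestine Lgr5 was at 0.19 ± 0.37 (adjusted p = 0.806) and against the colon at 0.84 ± 0.33 (adjusted p = 0.145), whereas Aqp5 was higher by at least 5.65 ± 0.43 (adjusted p = 6.77e-09) and 5.09 ± 0.38 (adjusted p = 8.28e-09), its levels there (4.34 and 4.90) being close to the array medians. The dimmer group of the genes below lay at 3.05 to 5.32, so those differences may be lower bounds too. Higher in the pylorus against both organs were the gastrokine gene Gkn2 (8.61 ± 1.17 and 8.12 ± 1.03), the gland mucin gene Muc6 (8.41 ± 0.98 and 7.98 ± 0.87), Tff2 (8.03 ± 1.13 and 7.63 ± 1.00) and Gast, which encodes gastrin (8.13 ± 0.22 and 7.76 ± 0.20). Lower than in the small intestine were the Paneth cell defensins Defa22 (-8.84 ± 1.00) and Defa21 (-8.48 ± 1.14), Mptx2 (-8.33 ± 0.74), Mmp7, a protease that activates defensins (-7.02 ± 0.48), and Olfm4, an intestinal stem cell marker (-6.74 ± 0.54). Lower than in the colon were the goblet cell genes Retnlb (-7.46 ± 0.94) and Reg4 (-7.09 ± 1.05) and the oxidase gene Nox1 (-5.44 ± 0.57).

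All 12 gastric identity genes were higher than in the small intestine (12 adjusted over the list alone, mean 5.70, adjusted p = 0.0302 with an estimated correlation). 11 of 12 were higher than in the colon (12 adjusted over the list alone, mean 5.46, adjusted p = 0.0133 with an estimated correlation). Mucous cell genes were higher in 9 and 7 of 10 (10 and 8 adjusted over the list alone, means 4.30 and 4.23, adjusted p = 0.0033 and 0.00484 with an estimated correlation). Paneth cell genes were lower than in the small intestine in 6 of 6 (6 adjusted over the list alone, mean -5.48, adjusted p = 0.0302 with an estimated correlation). Goblet cell genes were lower than in the colon in 10 of 12 (10 lower and 1 higher adjusted over the list alone, mean -3.59, adjusted p = 0.0631 with an estimated correlation). Intestinal identity genes were lower in 6 and 7 of 9 (7 and 8 adjusted over the list alone, means -2.80 and -2.53, adjusted p = 0.114 and 0.0708 with an estimated correlation). G2/M genes were lower in 20 and 13 of 22 (21 and 20 adjusted over the list alone, means -1.65 and -1.12, adjusted p = 0.042 and 0.0631 with an estimated correlation). G1/S genes were lower in 13 and 4 of 16 (15 and 14 adjusted over the list alone, means -1.24 and -0.90, adjusted p = 0.041 and 0.0575 with an estimated correlation). Camera called further lists against both organs. Pit cell (9 of 11 in each, means 5.51 and 4.59) and chief and parietal cell genes (5 of 7 in each, 4.12 and 4.50) were higher in the pylorus. So were tuft cell (2 and 3 of 18, 0.86 and 0.81), ER chaperone (8 and 4 of 14, 0.94 and 0.60) and pancreatic acinar genes (2 and 3 of 7, 1.39 and 1.31). Colonocyte genes were lower (3 of 7 in each, -1.89 and -3.06). Against the small intestine alone it called intestinal stem cell (8 of 18 lower and 2 higher, mean -0.92), enterocyte (8 of 17, -1.98) and goblet cell genes (4 of 12 lower and 2 higher, -1.97) lower. Against the colon alone it called Wnt target (2 of 16 higher and 1 lower, mean 0.35) and enteroendocrine genes (7 of 26 higher and 3 lower, 0.88) higher. None of these further lists was called with an estimated correlation, at an adjusted p between 0.0523 and 0.517. That estimate came from the fit holding the gastric-like whole colon array. It was 0.686 for pit cell and 0.849 for chief and parietal cell genes, against 0.191 and 0.034 in the DTR fit. Fry called all but tuft cell, colonocyte and goblet cell genes against the small intestine and Wnt target genes against the colon. In total 2752 genes were called against the small intestine, 1036 higher and 1716 lower, and 1580 against the colon, 644 higher and 936 lower. The first count was 1124 and 1480 without small intestinal Lgr5Hi replicate 1 and 2, and the second 1049 without colonic Lgr5Hi replicate 3.

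Whether the change from Lgr5Lo to Lgr5Hi cells itself differed between organs was tested as a difference of differences. By list mean it was most negative for cell cycle genes. Between pylorus and colon the G2/M mean was -1.51 (5 of 22 lower, 20 adjusted over the list alone, camera adjusted p = 2.91e-29, and adjusted p = 0.0253 with an estimated correlation), with Kif11 at -2.25 ± 0.39, Nusap1 at -2.05 ± 0.35 and Cenpe at -1.94 ± 0.35, all genes of the mitotic spindle. The G1/S mean was -1.17 (2 of 16 lower, 10 adjusted over the list alone, adjusted p = 0.0253 with an estimated correlation), with Hells at -2.35 ± 0.46 and Mcm6 at -1.84 ± 0.36. The mucous cell mean was 1.19 (1 of 10 higher, 4 adjusted over the list alone, adjusted p = 0.041 with an estimated correlation, and 0.0564 by fry), with Creb3l4 at 2.39 ± 0.37. Camera also called the ER chaperone genes higher (0 of 14, 1 adjusted over the list alone, mean 0.64, adjusted p = 0.157 with an estimated correlation, and 0.0564 by fry). Rsph9 (2.33 ± 0.38), Cxcl15 (2.37 ± 0.49) and Cacna2d1 (1.91 ± 0.40) were higher, the last 2 with both colonic gates below the array medians (2.89 to 3.67). Between pylorus and small intestine Slc9a3, a sodium-proton exchanger (4.01 ± 0.71), Afp (3.72 ± 0.46), Cacna2d1 (3.58 ± 0.46), Slc28a3 (2.77 ± 0.48) and Rsph9 (2.58 ± 0.43) were higher, and Cyp2e1 (-2.94 ± 0.37) and Cdc20 (-1.99 ± 0.35) lower. Afp and Cyp2e1 lay near the array medians in both pyloric gates (3.75 to 3.91), so these 2 differences rest on the small intestinal gates. The G2/M mean there was -1.29 (1 of 22 lower, 15 adjusted over the list alone) and the G1/S mean -1.04 (0 of 16, 4 adjusted over the list alone), each at an adjusted p of 0.107 with an estimated correlation and 0.0334 by fry. Camera also called enteroendocrine (0 of 26, also adjusted over the list alone, mean 0.63), ER chaperone (0 of 14, also adjusted over the list alone, 0.53), mucous cell (0 of 10, 4 adjusted over the list alone, 0.67) and enterocyte genes (0 of 17, also adjusted over the list alone, 0.80) higher. Intestinal stem cell genes (0 of 18, 3 adjusted over the list alone, mean -0.70) were called lower. None of these 5 lists was called with an estimated correlation, at an adjusted p between 0.142 and 0.464. Fry called none of them either. The groups of the genes named here were not required to be free of overlap. The difference was not called for Lgr5 (0.12 ± 0.46 against the colon, -0.46 ± 0.53 against the small intestine) or Aqp5 (1.45 ± 0.53 and 1.90 ± 0.60). With the replicate number as a block Aqp5 was called against the colon (adjusted p = 0.0408) and Cxcl15 was not (adjusted p = 0.0643).

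The test called 50 genes between pylorus and colon, 8 higher and 42 lower, and 7 between pylorus and small intestine, 5 higher and 2 lower. With the replicate number as a block the counts were 195 and 30, 48 and 7 of them shared, and camera then also called the immediate early genes (means 0.33 and 0.34). 1 fit over all 42 arrays called 231 and 62 and the fit without the gastric-like whole colon array 92 for the colon. The colon count was 20, 101 and 31 without pyloric Lgr5Hi replicate 4, Lgr5Lo replicate 3 and Lgr5Lo replicate 4, and 17, 5, 7 and 1 without colonic Lgr5Hi replicates 1 and 3 and Lgr5Lo replicates 2 and 3. The small intestine count was 4, 3, 16 and 3 without pyloric Lgr5Hi replicates 1 to 4, 4 and 19 without pyloric Lgr5Lo replicates 2 and 3, and 3, 40 and 3 without small intestinal Lgr5Hi replicates 1 and 2 and Lgr5Lo replicate 1. Of the called genes named, 0 of 9 against the colon and 3 of 7 against the small intestine kept their call without each array in turn, and quantile normalization lost Cxcl15 (adjusted p = 0.0507).

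**Figure D3:**
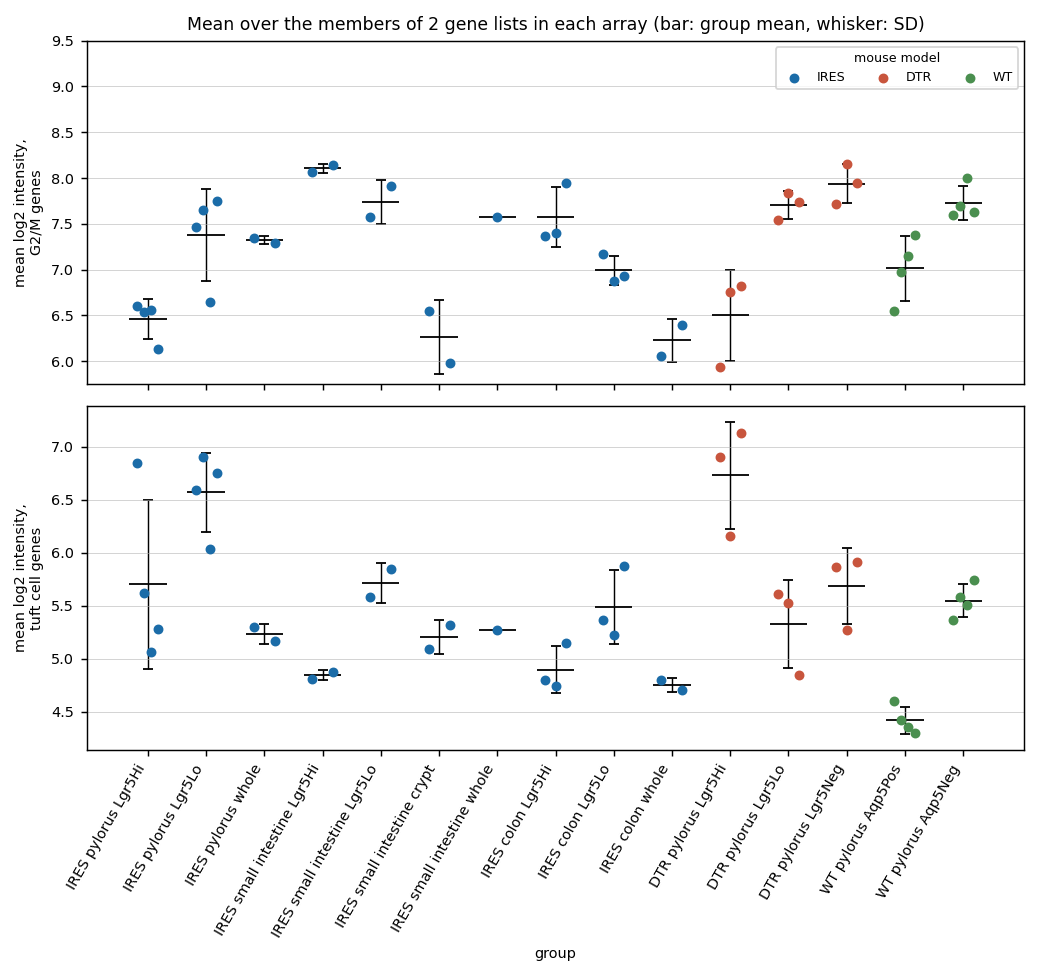
Mean log2 intensity over the members of the G2/M list (upper panel) and the tuft cell list (lower panel) in each array, by group on the horizontal axis and coloured by mouse model. The bar is the group mean and the whisker the SD. G2/M genes are at 6.46 in IRES pyloric Lgr5Hi cells against 7.38 in Lgr5Lo cells, and at 7.57 against 6.99 in the colon. Tuft cell genes are at 6.73 against 5.33 in the DTR gates and at 5.70 against 6.57 in the IRES gates.

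The stated purpose of the series was to find genes enriched in pyloric stem cells over other gastrointestinal populations. 41 genes were at least 2-fold higher in IRES pyloric Lgr5Hi cells than in each of 5 other sorted populations, namely pyloric Lgr5Lo cells and both gates of small intestine and colon, each with an adjusted p under 0.05. Ranked by the smallest of the 5 differences, the first were Serpina3n (2.58), the unnamed model Gm5086 (2.29, with 4.37 in pyloric Lgr5Lo cells), Rsph9 (2.29), Cacna2d1 (2.18), the ubiquitin ligase gene Rnf152 (2.16), Rgs5 (2.10), Slc9a3 (1.93), 2700046A07Rik (1.85) and the complement gene C4b (1.83). Aqp5 came next with 1.82, followed by Chad (1.81), Pitpnc1 (1.81), Itih2 (1.77), Colca2 (1.67), Scara3 (1.67), Asb4 (1.58), Kansl1l (1.57) and Bex4 (1.57). Cxcl15 (at least 2.70) and Tmem100 (at least 1.77) were left out of this order, because they lay below every array median in each of the 5 other populations (at most 3.23 and 3.56). Unsorted and crypt arrays were not part of the rule. Slc9a3 and Spg20, also in the set, averaged 9.55 and 6.71 in the crypt arrays, against 10.34 and 6.58 in pyloric Lgr5Hi cells. The set was chosen on the IRES arrays, and the arrays of the other models were independent of that choice. In the DTR line 40 of the 41 genes were called higher in Lgr5Hi than in Lgr5Neg cells and none lower, where 3.62 would be expected from the share of all genes called higher (2-sided Fisher's exact test, p = 1.85e-41). Genes are not independent replicates, and the background held dim genes as well. The Fisher p-values here therefore describe an overlap of genes and do not measure the spread between samples. 28 were higher in DTR Lgr5Hi than in Lgr5Lo cells (expected 0.83) and 28 in Lgr5Lo than in Lgr5Neg cells (expected 0.643). In wildtype cells sorted on Aqp5 protein, 15 were higher in Aqp5Pos cells and none lower (expected 0.224, Fisher's exact test, p = 2.59e-24), and 40 of 41 differences were positive. Cxcl15 was 1 of those not called there. The set held 64 genes with the replicate number as a block, the 41 included, of which 61 were higher in DTR Lgr5Hi cells, and 73 without pyloric Lgr5Hi replicate 3. The fit behind the 41 genes held the gastric-like whole colon array. Without that array the set was larger, and A4gnt (smallest difference 2.14), Cela1 (1.69) and Cblif (1.08) were among the genes gained.

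**Figure D4:**
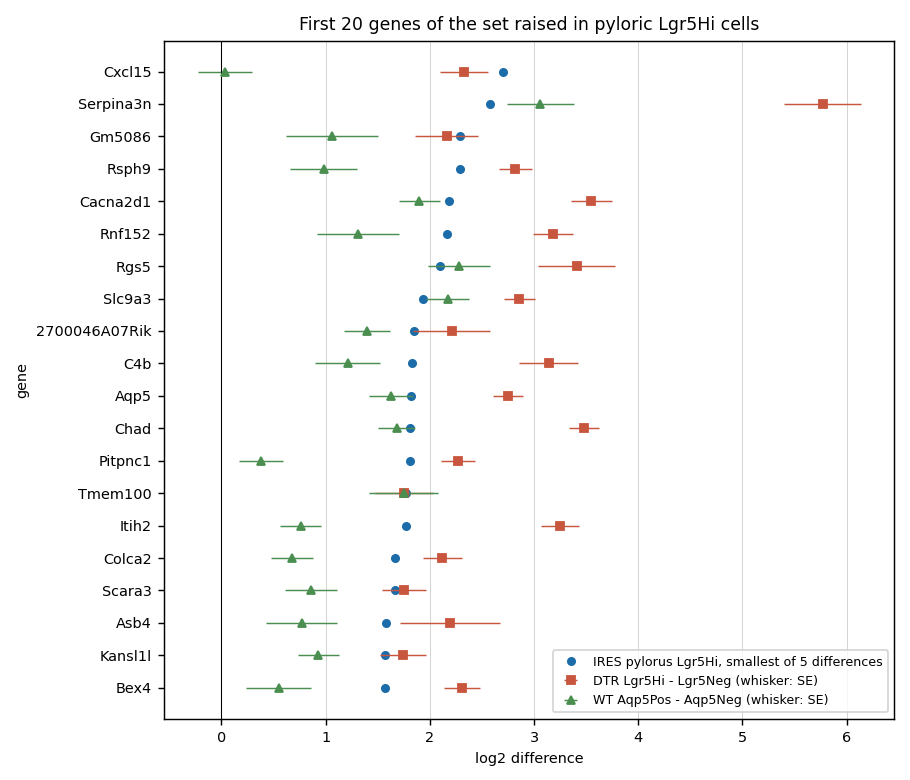
The first 20 genes of the set raised in IRES pyloric Lgr5Hi cells, with the log2 difference on the horizontal axis. Circles are the smallest of the 5 differences in the IRES line, a lower bound for Cxcl15 and Tmem100, squares the difference of DTR Lgr5Hi from Lgr5Neg cells and triangles that of wildtype Aqp5Pos from Aqp5Neg cells, with whiskers for the standard error. Serpina3n is highest in both independent models, at 5.77 and 3.06, the first a lower bound.

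Sorting wildtype pyloric cells by surface Aqp5 asks whether the antibody enriches the Lgr5-expressing population without a reporter. Aqp5Pos cells held more Lgr5 (1.96 ± 0.23, adjusted p = 0.00154) and Aqp5 (1.63 ± 0.21, adjusted p = 0.00245), in 4 of 4 arrays each. They also held more stem cell transcripts, and less of the transcripts of tuft and pit cells. Serpina3n (3.06 ± 0.32), Rgs5 (2.28 ± 0.30), Slc9a3 (2.17 ± 0.21), the protease inhibitor gene Mug1 (2.16 ± 0.27), Pigr, the epithelial receptor for secreted antibodies (2.00 ± 0.19), Cacna2d1 (1.90 ± 0.20), Lrg1 (1.87 ± 0.36), Tmem100 (1.75 ± 0.33) and A4gnt (1.69 ± 0.18) rose most. Rgs2 fell by 4.45 ± 0.38, the tuft cell genes Gnat3 and Rgs13 by 3.88 ± 0.35 and 3.43 ± 0.34, the acid pump genes Atp4a and Atp4b by 3.30 ± 0.55 and 2.76 ± 0.45 (Cblif, on the same list of chief and parietal cell genes, rose by 1.38 ± 0.17), and the alcohol dehydrogenase gene Adh7 by 3.21 ± 0.18. The adjusted p of these genes was at most 0.0172, and the arrays of the groups did not overlap. Aqp5Pos cells lay at 3.31 for Gnat3 and 3.27 for Rgs13, and Aqp5Neg cells at 2.91 for Tmem100. These levels lie under every array median, so the differences of these genes are lower bounds.

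Tuft cell genes were lower in 8 of 18 members (13 adjusted over the list alone, mean -1.13, adjusted p = 0.0348 with an estimated correlation), with Sh2d6 at -2.70 ± 0.23 and Dclk1 at -1.98 ± 0.21. Pit cell genes were lower in 6 of 11 (8 adjusted over the list alone, mean -1.03, adjusted p = 0.0497 with an estimated correlation), with Muc5ac at -2.00 ± 0.33 and Tff1 at -1.32 ± 0.19. Wnt target genes were higher in 3 of 16 (6 higher and 1 lower adjusted over the list alone, mean 0.49) and intestinal stem cell genes in 5 of 18 (7 higher and 1 lower adjusted over the list alone, mean 0.54). The same held for gland base genes in 4 of 13 (7 adjusted over the list alone, mean 0.59), and each list had an adjusted p of 0.0497 with an estimated correlation. Cd44 (1.47 ± 0.20), Sox9 (1.20 ± 0.20) and Smoc2 (1.21 ± 0.22) were among them. Mucous cell genes were higher in 4 of 10 (8 adjusted over the list alone, mean 0.80, adjusted p = 0.0568 with an estimated correlation), with Muc6 at 1.22 ± 0.16. G2/M genes were lower in 4 of 22 (13 adjusted over the list alone, mean -0.72, adjusted p = 0.138 with an estimated correlation), with Ccnb2 at -1.27 ± 0.20. G1/S genes fell in 1 of 16 (6 adjusted over the list alone, mean -0.49, adjusted p = 0.1 with an estimated correlation), and gastric identity genes in 5 of 12 (6 lower and 1 higher adjusted over the list alone, mean -0.55, adjusted p = 0.138 with an estimated correlation). The gastric identity list shares members with the pit cell list, Tff1 among them, so its fall is in part the same result. Fry called the mucous cell, G2/M, G1/S and gastric identity lists, at an adjusted p of 0.0184 or less. Camera also called Paneth cell genes higher (0 of 6, 2 adjusted over the list alone, mean 0.70, adjusted p = 0.107 with an estimated correlation) and enteroendocrine genes lower (1 of 26, 5 adjusted over the list alone, mean -0.38, adjusted p = 0.456 with an estimated correlation, and 0.185 by fry). In total 621 genes were called, 121 higher and 500 lower, and 387 at 2-fold or more. Values in the Aqp5Pos arrays were less spread, with lower quartiles of 2.98 to 3.13 against 2.92 to 2.96 in Aqp5Neg arrays. The upper quartiles were 5.47 to 5.54 against 5.60 to 5.65. Quantile normalization gave 448 calls with 135 higher. 1 fit over all 42 arrays gave 1170 and lost Atp4b, Muc6, Tff1, Muc5ac and Cblif among the 27 genes named, and leaving out each array in turn lost Lrg1, Tmem100 and Smoc2. Those lost in the single fit lay at 10.85 to 12.92 in the gastric-like whole colon array, against 3.80 to 4.09 in whole colon 2. That spread enters the single fit. The count was 297, 255, 217 and 196 without Aqp5Neg replicates 1, 2, 3 and 4.

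The changes of the 3 models were then set side by side across all 22180 genes. The models share no arrays, and genes are not independent replicates, so the correlations describe the arrays and carry no p-value. Pearson's r was 0.45 (Spearman's rho 0.32) between IRES and DTR Lgr5Hi against Lgr5Lo, 0.53 (rho 0.37) between IRES Lgr5Hi against Lgr5Lo and DTR Lgr5Hi against Lgr5Neg, and 0.37 (rho 0.24) between IRES Lgr5Hi against Lgr5Lo and the wildtype sort. DTR Lgr5Hi against Lgr5Neg and against Lgr5Lo gave 0.47 (rho 0.31) and 0.40 (rho 0.30) with the wildtype sort. Between IRES and DTR Lgr5Hi against Lgr5Lo 59 genes were called higher in both (2.71 expected from independent lists), 112 lower in both (5.77 expected) and 1 in opposite directions. Between DTR Lgr5Hi against Lgr5Neg and the wildtype sort 79 were higher in both (10.7 expected), 318 lower in both (47.4 expected) and 21 opposite. Lgr5, Aqp5, Serpina3n, Rgs5 and Cacna2d1 were called higher in these 3 comparisons of IRES Lgr5Hi against Lgr5Lo, DTR Lgr5Hi against Lgr5Neg and wildtype Aqp5Pos against Aqp5Neg.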

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

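The tests of the 3 patterns weighed here, and the counts over splits that part each replicate number, were chosen after the results were seen, while the other counts of splits were planned. Choosing to list gene lists that passed camera with both correlations was also done with the values known.

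The whole colon array numbered 1, which no comparison of genes used, had a gastric profile. Its gastric identity genes averaged 9.90 against 4.73 in whole colon 2, and 9.21 to 10.68 in the 27 pyloric arrays. Colon tissue mixed with stomach, and a swap with another array of the series, were argued against by the intestinal identity genes, at 5.04 in this array, 5.12 to 6.47 in the pyloric ones and at least 7.70 in the 14 other intestinal and colonic ones, of which none was out of place. The bound of that test was redrawn after its first result, because 5.04 lay just under the lowest pyloric value of 5.12, and the test of a pyloric sample was added with the Gast and Aqp5 values already seen. A pyloric sample was argued against by Gast at 5.13 (pyloric arrays 6.23 to 12.89) and Aqp5 at 5.20 (6.95 to 10.65), so a stomach sample from outside the pylorus under a colon label may be the source, with Atp4a at 12.69 (pyloric highest 11.57) and gastric identity genes at 9.90, and no biological explanation was tested.

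Camera at the preset correlation called cell cycle genes lower in pyloric Lgr5Hi than Lgr5Lo cells (adjusted p = 0.101 for both lists with an estimated correlation). It called them higher in colonic ones (adjusted p = 0.0979 for both with an estimated correlation, and no colonic gene was called). Fry called the pyloric fall (adjusted p = 0.0109 for G2/M and 0.0208 for G1/S genes) and not the colonic rise (0.132 for both). With an estimated correlation only the difference of differences held, at -1.51 for G2/M and -1.17 for G1/S genes (adjusted p = 0.0253 for both). It was -1.54 for G2/M genes after quantile normalization. That step moved the median over all genes only from -0.034 to -0.004. The result thus argues only against scaling left between arrays after the authors' processing. DTR cells had a G2/M difference of -1.20 (21 of 22 members lower, and adjusted p = 0.115 for the list with an estimated correlation), which argues against an effect of the IRES pyloric arrays alone. The lowest mean of the immune, stromal and endothelial lists in the IRES pyloric comparison was -0.05. Several of these markers lay near the array medians in both gates, such as Cd79a (3.63 and 3.90) and Col1a2 (3.75 and 3.62). Ptprc (-0.80 ± 0.38) leaned lower and C1qc (0.44 ± 0.19) higher, neither called, so this test does not decide on such cells in the Lgr5Lo gate. Of 100 drawn splits 1, the real one, gave a G2/M mean as far from 0, the highest other being 1.32, and of the 64 splits that part each replicate number 1 did, the highest other being 1.46. Both shares lie under 0.05 and are the smallest that these splits can give. A difference between the tissues may remain as an untested biological explanation, and the gates of the tissues were not compared.

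Camera at the preset correlation called tuft cell genes higher in DTR Lgr5Hi than Lgr5Lo cells (13 of 18 members, and adjusted p = 0.115 with an estimated correlation) and lower in IRES Lgr5Hi cells (2 of 18, and adjusted p = 0.185 with an estimated correlation). Within a line neither list call held with an estimated correlation, while fry called both (adjusted p = 0.0189 and 0.0373). The difference between the lines was 2.27 (camera adjusted p = 3.04e-39, and adjusted p = 0.000216 with an estimated correlation). Quantile normalization gave 1.39 in DTR and -0.85 in IRES cells, which argues only against scaling left after the authors' processing. Without each array in turn the means stayed at 1.16 to 1.69 and -1.25 to -0.65, which argues against a single array. If the gates held different shares of tuft cells, members would move in proportion, and the correlation across the 18 members of the DTR changes with the reverse of the IRES changes was 0.37 (Spearman's rho 0.54, over the bound of 0.5 set for this test; permutation p of the first 0.13), and 0.45 (rho 0.68, permutation p = 0.059) with the reverse of the wildtype changes, which leaves this open. Reporter line, and any difference of gate or array batch that goes with it, cannot be told apart. With 1 fit over all arrays 17 genes differed between the lines, 16 higher and 1 lower, and 1012 at an unadjusted p under 0.05.

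The difference of differences called 7 genes between pylorus and small intestine and 50 between pylorus and colon, and the gland mucous cell mean there was 1.19. For the 50 genes 1 of 100 drawn splits gave as many, the highest other 7, and 1 of the 64 splits that part each replicate number, the highest other 39. These shares are under 0.05, again the smallest possible. The share was also under 0.05 for the 1580 of pyloric against colonic Lgr5Hi cells (1 of 35, highest other 745) and the 621 of the wildtype sort (1 of 35, highest other 1). Equally numbered pyloric and colonic Lgr5Hi arrays did not deviate together (r = -0.03, -0.03 and -0.22), so all 35 splits were counted there. For IRES pyloric Lgr5Hi against Lgr5Lo, 1 of 35 splits gave as many as the real 330, the highest other 108, but only 8 of them part each replicate number as the real one does. Those are too few for a share under 0.05, with 17 as the highest other. The 10 splits of 3 arrays against 3 are too few for a share under 0.05. The real counts were 4062, 1102 and 488 in the DTR comparisons, each with 0 as the highest other, and in the colon 10 of 10 splits gave as many as the real count of 0, with 0 as the highest other. In the whole small intestine array, which no comparison of genes used, Lgr5 was at 7.09, above 4.81 and 5.04 in the crypts.

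Of 242 values in groups of 4 arrays 19 had 1 array far from the rest, and chance picks about 1 in 20 groups. In IRES pyloric Lgr5Hi cells, replicate 4 was low for G2/M genes (6.13, the others 6.54 to 6.60) and Birc5 (6.45, 6.94 to 7.03) and high for immediate early genes (7.71, 6.33 to 6.55), and replicate 3 was high for Cyp2e1 (4.43, 3.60 to 3.62). In IRES pyloric Lgr5Lo cells, replicate 3 was low for Serpina3n (4.58, 6.23 to 6.44) and Wnt target genes (5.43, 5.82 to 5.85), and replicate 4 was high for immediate early genes (7.00, 6.34 to 6.41). In Aqp5Neg cells, replicate 3 was high for Atp4a (10.97, 9.30 to 9.53) and Atp4b (10.92, 9.40 to 9.59) and low for Lrg1 (5.40, 5.97 to 6.08), and replicate 4 was high for Gnat3 (8.07, 6.82 to 6.98). In Aqp5Pos cells, replicate 1 was high for Gnat3 (4.34, 2.92 to 3.00) and enteroendocrine genes (5.41, 4.79 to 4.86) and low for Muc6 (12.20, 12.31 to 12.32) and ER chaperone genes (8.02, 8.31 to 8.36). Replicate 2 was high for enterocyte (5.55, 5.24 to 5.28) and goblet cell genes (5.82, 5.50), and replicate 4 was low for Sh2d6 (3.70, 4.52 to 4.55) and high for Ccnb2 (8.45, 7.71 to 7.82).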

How the results depend on the processing

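The fits without the gastric-like whole colon array, the block and quantile normalization for lists, and the block for correlations were chosen after the data were seen; the others were planned. No called value changed sign. Counts moved by more than 1.5 times as follows, and the cause was not tested except where fewer genes qualify. One fit over all 42 arrays gave 1515, 132 and 24 calls in DTR Lgr5Hi against Lgr5Neg, Lgr5Hi against Lgr5Lo and Lgr5Lo against Lgr5Neg, 780, 155 and 20 in IRES pylorus, small intestine and colon Lgr5Hi against Lgr5Lo, 62 and 231 in the differences of differences with small intestine and colon, and 1170 in WT. That fit held the gastric-like whole colon array, whose share in these counts was not tested. The block gave 756 in the pylorus, 93 in the small intestine, 30 and 195 in the differences of differences, and 64 genes in the pyloric set, 61 of them higher in DTR cells. A 2-fold threshold left 1247, 369 and 191 in DTR and 387 in WT. Removing dim probe sets left 11 in the small intestine, and the mean of all probe sets gave 2 in the colon. Without the gastric-like array the counts were 518, 69 and 92 in pylorus, small intestine and the difference with the colon. Leaving out each replicate in turn gave 325 to 1036 and 181 to 367 in the latter DTR comparisons (3001 to 3754 in the first), 173 to 414 in IRES pylorus, 304 to 1307 against whole pylorus, 2 to 89 in small intestine, 0 to 1 in colon, 1124 to 2606 and 1049 to 1587 between Lgr5Hi cells of pylorus and small intestine or colon, 3 to 40 and 1 to 101 in the differences of differences, 196 to 893 in WT and 28 to 73 in the pyloric set. Of 171 calls of named genes, a gene counting once per comparison, 111 were kept in each alternative run for them. Of 2478 tests of named genes 172 lost and 5 gained a call, 135 of the losses without 1 replicate. Of 1456 list tests 158 lost and 38 gained a call, 107 of the losses with an estimated correlation and 43 by fry. Of 87 correlations between models 12 moved, 5 with dim probe sets removed (0.47 to 0.64) and 7 without 1 replicate (0.24 to 0.48). Signal over background limits dim genes, whose removal moved the count of calls in the small intestine alone, and all 5 correlations.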

Other observations

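Muc5ac lay between 8.16 and 11.13 in the IRES pyloric Lgr5Hi arrays and between 4.70 and 6.41 in the DTR ones. These differ in line and may differ in gate and array batch, and this difference in level was not tested. In the difference between the lines over Lgr5Hi against Lgr5Lo cells, chosen for testing after the data were seen, camera with the preset correlation also called surface pit cell genes (-1.06), gastric identity genes (-0.73), gland mucous cell genes (-0.38), G1/S (-0.55) and G2/M genes (-0.28) lower and enteroendocrine (0.47) and enterocyte genes (0.56) higher. With an estimated correlation none of these was called, at adjusted p between 0.308 and 0.847.

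The unsorted small intestine array and the crypts, which entered no comparison of genes, are given as values for whole, crypt 1 and crypt 2. Olfm4 was at 10.95, 9.28 and 8.68, Smoc2 at 7.74, 6.24 and 5.10, Mki67, a proliferation marker, at 8.75, 7.96 and 7.14, and the mean of intestinal stem cell genes at 7.01, 5.84 and 5.53. The brush border genes Alpi and Sis were at 10.50, 11.95 and 11.97 and at 9.56, 11.73 and 11.62, and the mean of enterocyte genes at 9.01, 11.03 and 11.15. Paneth cell genes averaged 10.91, 9.62 and 8.92 and G2/M genes 7.57, 6.55 and 5.98. Stem cell, Paneth cell and cycle genes were thus lower and enterocyte genes higher in the arrays titled crypt, and the population field of those arrays reads whole. Xist was at 8.34, 3.60 and 2.89, and the Y-linked gene Eif2s3y at 4.20, 7.23 and 7.56.

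The whole colon array numbered 1 correlated at 0.962 across genes with whole pylorus and at 0.908 with whole colon 2. Muc5ac was at 12.50 and 4.05 in whole colon 1 and 2, Atp4b at 12.37 and 4.09, Cblif at 11.21 and 3.80, Pgc at 13.32 and 4.45, Cdx2, an intestinal transcription factor, at 4.43 and 8.04, and Car1, a colonic carbonic anhydrase, at 2.50 and 11.61. Atp4a, at 12.69 and 4.98 in whole colon 1 and 2, had a standard error of 0.96 in IRES pyloric Lgr5Hi against Lgr5Lo cells. Its difference there was -2.53 and was not called (adjusted p = 0.223), although the arrays of the gates did not overlap. Without whole colon 1 the pyloric set held 57 genes, 56 of them higher in DTR Lgr5Hi than Lgr5Neg cells. In wildtype Aqp5Pos cells 20 were higher and 1 lower, Lncpint, at -1.60 (adjusted p = 0.00181), which is named here after its value was seen.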
